A study of Mus musculus with 2 samples.

How the data were processed

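Total RNA was extracted with a mirVana kit, per the labels' protocols, from neural tubes of mouse embryos at embryonic day 12.5, and a SMARTer Ultra Low RNA kit manual is among the protocols linked there. Both libraries form 1 group. Each had 10 ng of RNA longer than 200 nucleotides and added spike-in controls, per the labels. No batch or date of library preparation is given in the labels, so no split by batch was made. The replicate numbers are those of the labels, and the values are from 1 library each.

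The authors deposited a table per gene and a table per transcript for each library. The title of the series marks it as superseded by a later one, which was not used here, and values there may differ. Per the deposited read-me text, the values come from alignments to the transcriptome with assembly mm10 and GENCODE annotation M4. The program that made them is not given in the sources used here. Expected counts, per the file headers, are estimated reads per gene or transcript, which need not be whole. In replicate 1, 85.2% of genes had a value within 0.005 of a whole number. TPM and FPKM values, per the file headers, are corrected for effective length and depth. The deposited percent values give each transcript's share within its gene, in a version from the maximum likelihood estimate and a version from the posterior mean. The deposited TPM bounds are credibility intervals whose level is not stated. For the 1 spike-in control examined, the effective length was 99 nucleotides below the length in both libraries. TPM of short rows is uncertain, and 3905 rows with an effective length under 100 held 0.804% of TPM in replicate 1 and 0.775% in replicate 2, but 0.0165% and 0.0153% of counts. Whether counting used strand is not given in the sources used here, so antisense and overlapping genes cannot be separated.

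The gene tables held 69691 rows, of which 43346 were mouse genes, 97 spike-in controls and 26248 short rows named by number. Names, biotypes and coordinates (1-based) were taken from GENCODE M21 on GRCm38, the same assembly with later gene models, by matching identifiers without version. In this way 42462 genes were matched. The 884 unmatched genes held 0.301% and 0.272% of gene counts in replicates 1 and 2 and stayed in library totals and gene counts without a name. Where a transcript was named, its exons and coding length are those of M21. Number-named and spike-in rows were left out of all gene counts and of the library totals used for scaling.

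Depth was 32612423 expected counts in replicate 1 and 34555002 in replicate 2. With a floor of 3 counts, a count of 0 allows up to 0.0949 and 0.0895 CPM of gene counts. The reads carried no molecular identifiers in these tables, so floors and intervals cover counting error only.

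A gene or transcript was detected at 1 TPM or more in both libraries. Ratios are on the log2(TPM + 1) scale, replicate 2 over replicate 1, which understates differences of low genes. Agreement between libraries was measured over genes with a mean of at least 1 TPM, and their counts were compared with sampling noise by a chi-square over genes with at least 20 summed counts. The biological coefficient of variation was estimated with edgeR on rounded expected counts (17075 genes). TMM factors were 0.997 and 1.003, and DESeq2 size factors 0.971 and 1.03. For each of 38 gene lists (474 distinct genes, all matched), the median level and the number detected were taken. The median log2 ratio of members with a mean of at least 1 TPM was ranked as a percentile among 10000 random lists of the same size matched on mean level in 20 bins. Gene lists were compared within each library as a difference of medians of log2(TPM + 1). Shares of counts have exact (Clopper-Pearson) 95% binomial intervals. Transcript use was compared over genes with at least 5 TPM in both libraries and 2 or more transcripts. With 1 group, no p-value was computed.

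The lists, the comparisons, the alternatives and the rule for named genes were set before the data were examined, except where the text says otherwise. The rule takes the 3 highest members of each list, up to 3 members under 1 TPM in both libraries, all Hox genes, and the 15 nuclear protein-coding genes with the highest mean TPM. It also takes the 8 protein-coding genes with the largest ratio in each direction (mean of at least 5 TPM and 100 expected counts in the higher library), the genes of a fixed isoform set with at least 5 TPM in both libraries, and the 2 highest members of lists in no comparison. Some genes that the rule takes are not reported here.

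The scripts were tested on simulated data. Over 15876 genes drawn at the libraries' means and depths for the ratio of replicate 2 over replicate 1, all genes changed 4-fold or 0.25-fold passed the 2-fold limit (100%), as did 0.829% of unchanged genes, and none changed 1.5-fold did (0%). The changed genes, 50 per fold, all had a mean of at least 5 TPM and a mean of at least 100 counts. Whether changes of lower genes pass the limit was not tested. Of 200 unchanged lists of 12 genes, 7.5% fell outside the middle 95% of random lists. Alternatives were other pseudocounts, detection thresholds, low-value filters, bins, units (FPKM, CPM), TMM or DESeq2 scaling, the list mean, subsets of list members, other limits for transcript use, and each library alone. Versions were R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.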

Results

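Libraries were made from RNA of the neural tube of mouse embryos at embryonic day 12.5, extracted as total RNA. The neural tube is the embryonic structure that forms the brain and spinal cord. The labels give 1 group of 2 biological replicates. Replicate 1 was pooled from 120 embryos and replicate 2 from 88, and each library was made from 10 ng of RNA longer than 200 nucleotides. Both pools held embryos of both sexes and carry the same donor identifier. The gene tables summed to 32612423 expected counts in replicate 1 and 34555002 in replicate 2. Of these, 31610805 and 33530172 fell on mouse genes. The design holds no second tissue, stage or treatment, so the comparisons below are between gene groups within the tissue and between the 2 pools, and no p-value is given. Levels are deposited TPM values (transcript abundance corrected for length and depth), as mean ± SD (n = 2). For lists this SD is between the libraries and does not measure the spread of members. Quartile ranges of members overlapped in every comparison of 2 lists below except Hox genes against forebrain and midbrain factors.

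In all, 15181 genes reached 1 TPM in both libraries, of which 13333 were protein-coding, 332 antisense and 264 long intergenic noncoding RNA genes. A further 1085 genes reached it in 1 library only, and 32787 transcripts reached it in both. The 15 highest nuclear protein-coding genes were led by the cytoskeletal genes Tuba1a (9820 ± 28.6 TPM), Actb (5913 ± 114 TPM) and Tmsb4x (5434 ± 580 TPM). They also held the globin genes Hbb-y (5365 ± 94.6 TPM) and Hba-a2 (4497 ± 247 TPM), the microtubule regulator Stmn1 (4085 ± 71.3 TPM) and the imprinted neuronal gene Nnat (2755 ± 118 TPM). The remaining 8 were Ftl1, Tmsb10, Ppia, Ubb, Actg1, Hist1h2ap, H3f3a and Eef1a1, between 2717 and 4917 TPM. Hba-a2 and Hist1h2ap have near-identical copies among which reads may have been divided, so their single levels are uncertain.

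The first comparison asked where along the head-to-tail axis the tissue lies. Hox genes, which mark hindbrain and spinal levels, were high, and factors of the forebrain and midbrain were near 0. The median Hox gene stood at 27.8 ± 1.88 TPM over 39 genes, against 0.13 ± 0.00707 TPM over 20 forebrain and midbrain factors. The difference of medians was 4.67 ± 0.09 on the log2(TPM + 1) scale, larger than the difference between the libraries (4.73 and 4.61). In both libraries 36 of 39 Hox genes reached 1 TPM, against 7 of 20 regional factors, and 11 regional factors stayed under 1 TPM in both. Among the higher regional factors were Lhx2 (5.92 ± 0.361 TPM) and En1 (3.34 ± 0.184 TPM), both also factors of spinal interneurons. Tbr1 (0.105 ± 0.0212 TPM) and Emx1 (0.1 ± 0.0424 TPM), factors of the cortex, stayed near 0. Vax1 had 3 expected counts in replicate 1 and 0 in replicate 2, where a count of 0 allows up to 0.0895 CPM of gene counts. Otx2 and Nkx2-1, chosen after their values were seen, stood at 0.07 ± 0 and 0 ± 0 TPM.

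**Figure D1:**
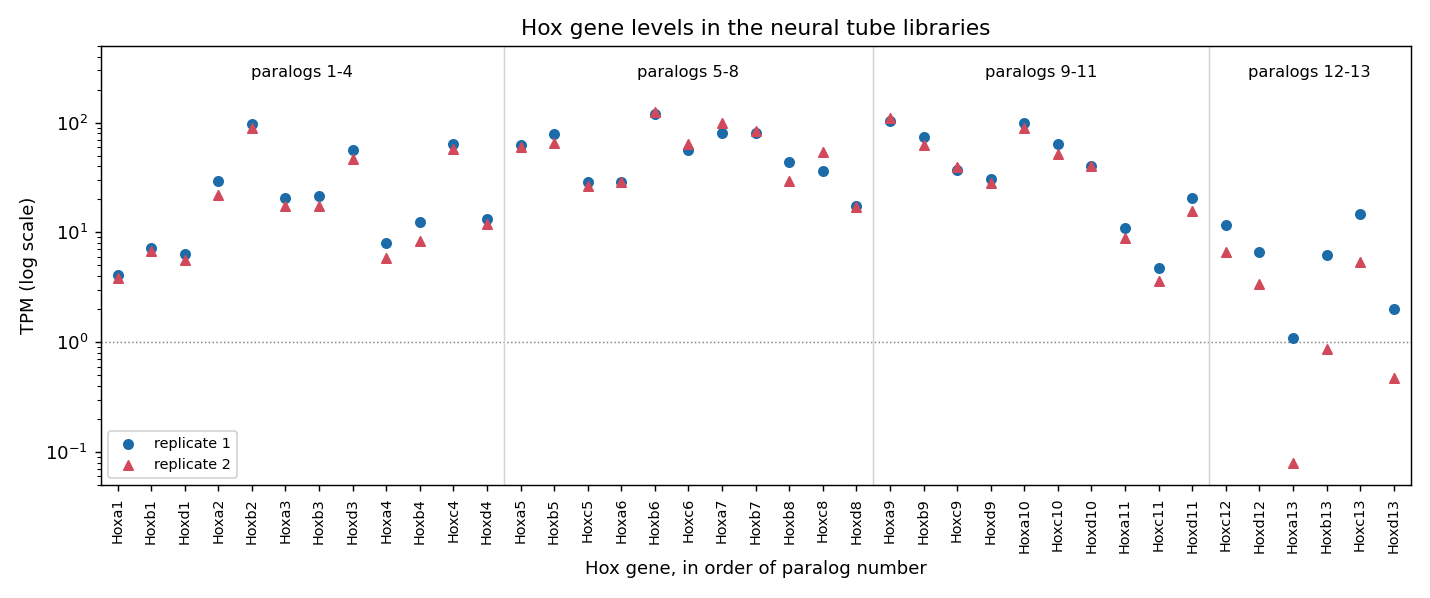
TPM of the 39 Hox genes on a log axis, in order of paralog number, with circles for replicate 1 and triangles for replicate 2 and a dotted line at 1 TPM. The 3 genes that do not reach 1 TPM in both libraries are Hoxa13, Hoxb13 and Hoxd13, which lie above 1 TPM in replicate 1 and below it in replicate 2.

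Among the Hox genes those in the middle of the clusters held the largest share of TPM. Paralogs 5-8, which mark cervical and thoracic levels, held 44.2 ± 2.88% of all Hox TPM, paralogs 9-11 held 32.0 ± 0.338%, paralogs 1-4 held 21.7 ± 1.39% and paralogs 12-13 held 2.00 ± 1.15% (2.82% in replicate 1 and 1.19% in replicate 2). By expected counts, which are not corrected for length, paralogs 5-8 (38.3 ± 2.36%) and 9-11 (36.0 ± 0.227%) were closer. The highest single genes were Hoxb6 (ENSMUSG00000000690, chromosome 11, 96292476 to 96301569; 123 ± 3.48 TPM), Hoxa9 (ENSMUSG00000038227, chromosome 6, 52223100 to 52231089; 106 ± 4.23 TPM), Hoxa10 (94.0 ± 6.43 TPM) and Hoxb2 (93.9 ± 5.43 TPM). By cluster, Hoxb (chromosome 11, 96194316 to 96368256) held 35.4 ± 1.01%, Hoxa (chromosome 6, 52155590 to 52260880) 30.7 ± 1.24%, Hoxc (chromosome 15, 102921103 to 103036852) 21.5 ± 0.438% and Hoxd (chromosome 2, 74668310 to 74765142) 12.5 ± 0.659%. Several Hox genes overlap one another or antisense transcripts, and the sources used here do not say whether counting used strand, so shares of single genes are less certain than sums.

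Neuronal and progenitor genes were both abundant. The 16 pan-neuronal genes had a median of 313 ± 22.8 TPM and the 16 neural progenitor genes one of 84.9 ± 0.813 TPM, a difference of medians of 1.89 ± 0.08 on the log2 scale. All 32 genes were detected in both libraries. The highest neuronal genes were the tubulin Tubb3 (1017 ± 18.9 TPM), the neurofilament gene Nefl (658 ± 82.9 TPM) and the microtubule regulator Stmn3 (545 ± 10.8 TPM). The highest progenitor genes were the fatty acid binding protein Fabp7 (1503 ± 48.2 TPM), the intermediate filament Vim (962 ± 35.9 TPM) and the Notch target Hes5 (333 ± 8.10 TPM). Without correction for transcript length, in CPM, the difference was 0.96.

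Dorsal patterning factors stood above ventral ones. The median of 15 dorsal progenitor factors was 11.3 ± 1.52 TPM against 2.87 ± 0.00707 TPM for 14 ventral ones, a difference of medians of 1.67 ± 0.18 on the log2 scale. The quartiles of members ran from 3.83 to 35.07 TPM for dorsal and from 2.075 to 9.87 TPM for ventral factors. Among the higher dorsal factors were the proneural gene Neurog2 (43.5 ± 3.46 TPM) and the paired-box gene Pax3 (37.2 ± 0.615 TPM), while the roof plate signal Gdf7 was at 0.34 ± 0.0141 TPM. Neurog2 is also expressed outside the dorsal domain. The ventral list was led by the guidance cue Ntn1 (39.4 ± 0.262 TPM), Irx3 (18.8 ± 1.68 TPM) and the V0 progenitor factor Dbx1 (12.4 ± 2.16 TPM). Foxn4, a factor of V2 progenitors, and Nkx2-9 stayed under 1 TPM in both libraries. The list medians of interneuron factors stood in the same order. The 18 factors of dI1 to dI6 neurons had a median of 11.2 ± 1.39 TPM and the 14 factors of V0 to V3 neurons one of 5.17 ± 0.400 TPM, a difference of 0.97 ± 0.06, and 1 gene, Foxd3, stands in both lists. Isl1 (133 ± 32.1 TPM), Pou4f1 (107 ± 17.3 TPM) and Tlx3 (61.2 ± 11.3 TPM) led the dorsal list, and all 3 are also sensory ganglion genes. Not every member of the dorsal list is particular to dorsal interneurons. The difference was not taken without such members, so it need not reflect dorsal interneurons. Foxp2 (21.9 ± 0.113 TPM), Lhx3 (16.9 ± 4.27 TPM) and Gata3 (9.77 ± 0.368 TPM) led the ventral list, and Sim1, a V3 factor, was at 0.94 ± 0.0707 TPM. The 16 motor neuron genes had a median of 17.3 ± 2.71 TPM, led by Isl1, the neurofilament Prph (108 ± 34.0 TPM) and the retinoic acid enzyme Aldh1a2 (79.1 ± 5.81 TPM).

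The list of inhibitory transmission genes had a higher median than that of glutamate transmission genes. The median of 12 GABA and glycine genes was 14.0 ± 0.0389 TPM against 8.27 ± 1.10 TPM for 11 glutamatergic genes, and the glutamatergic list was lower by a difference of medians of -0.70 ± 0.18 on the log2 scale (-0.82 in replicate 1 and -0.57 in replicate 2). The inhibitory list was led by the GABA-synthesising enzyme Gad2 (33.4 ± 4.95 TPM). Gad1, a related enzyme, stood at 15.9 ± 2.33 TPM and the vesicular transporter Slc32a1 at 3.26 ± 0.481 TPM, both chosen after their values were seen. The glutamatergic list was led by the receptor subunit Gria2 (40.8 ± 0.240 TPM), the vesicular glutamate transporter Slc17a6 (38.1 ± 2.15 TPM) and Grik2 (12.2 ± 1.03 TPM). Slc17a8, another vesicular transporter, was at 0.19 ± 0.0424 TPM.

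Genes of the astrocyte lineage stood above those of the oligodendrocyte lineage, with list medians of 25.4 ± 1.51 and 3.58 ± 0.103 TPM over 12 genes each and a difference of medians of 2.39 ± 0.09 on the log2 scale. By list means the difference was 1.16. The astrocyte list was led by genes that radial progenitors also express, Glul (104 ± 4.42 TPM), Gja1 (103 ± 1.41 TPM) and Slc1a3 (69.5 ± 1.36 TPM). The 3 members under 1 TPM in both libraries were markers of mature astrocytes, with S100b at 0.75 ± 0.0283, Aqp4 at 0.38 ± 0.0849 and Gfap at 0.08 ± 0.0283 TPM. Among the higher oligodendrocyte genes were Cnp (27.6 ± 0.332 TPM) and Sox10 (25.5 ± 5.11 TPM). Sox10 also marks neural crest and Schwann cells, and the myelin gene Mag was at 0.815 ± 0.233 TPM.

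The tissue also held transcripts of other cell types. Of 138 distinct marker genes of 11 other cell types, 118 reached 1 TPM in both libraries. Of the 138, 16 also stand in a neural list, among them Fabp7, Gap43 and Isl1, and 103 of the other 122 were detected. Erythroid genes were the highest, with a median of 370 ± 13.7 TPM, and all 12 were detected. Pericyte and meningeal genes had a median of 12.6 ± 0.0636 TPM (13 of 14 detected), with the collagens Col3a1 at 409 ± 16.1, Col1a1 at 177 ± 5.18 and Col1a2 at 171.3 ± 6.14 TPM far above it. The median endothelial gene stood at 19.6 ± 0.976 TPM (11 of 12 detected) and the median neural crest and Schwann cell gene at 23.3 ± 2.00 TPM (13 of 13). The median sensory ganglion gene stood at 15.2 ± 4.26 TPM (15 of 15), the median muscle and somite gene at 12.5 ± 3.62 TPM (15 of 16) and the median sclerotome and cartilage gene at 11.4 ± 0.718 TPM (9 of 12). Macrophage and microglia genes had a median of 7.26 ± 0.516 TPM (12 of 13), led by the complement gene C1qb (27.9 ± 1.41 TPM). Epidermis (2.64 ± 0.240 TPM, 9 of 11), liver and gut (0.915 ± 0.346 TPM, 5 of 11) and choroid plexus (0.752 ± 0.124 TPM, 4 of 10) were lowest. The liver transcripts Apoa2 (5.36 ± 1.23 TPM) and Afp (3.01 ± 1.22 TPM) and the epidermal keratin Krt5 (11.01 ± 0.509 TPM) were nevertheless counted in both libraries. The highest liver and gut member was Sox17 (11.6 ± 0.820 TPM). The 4 detected choroid plexus members were Msx1, Foxj1, Lmx1a and Aqp1, and Msx1 and Lmx1a also stand in the dorsal progenitor list. The other 6, among them Ttr and Folr1, stayed under 1 TPM in both libraries, so this list does not show choroid plexus tissue.

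**Figure D2:**
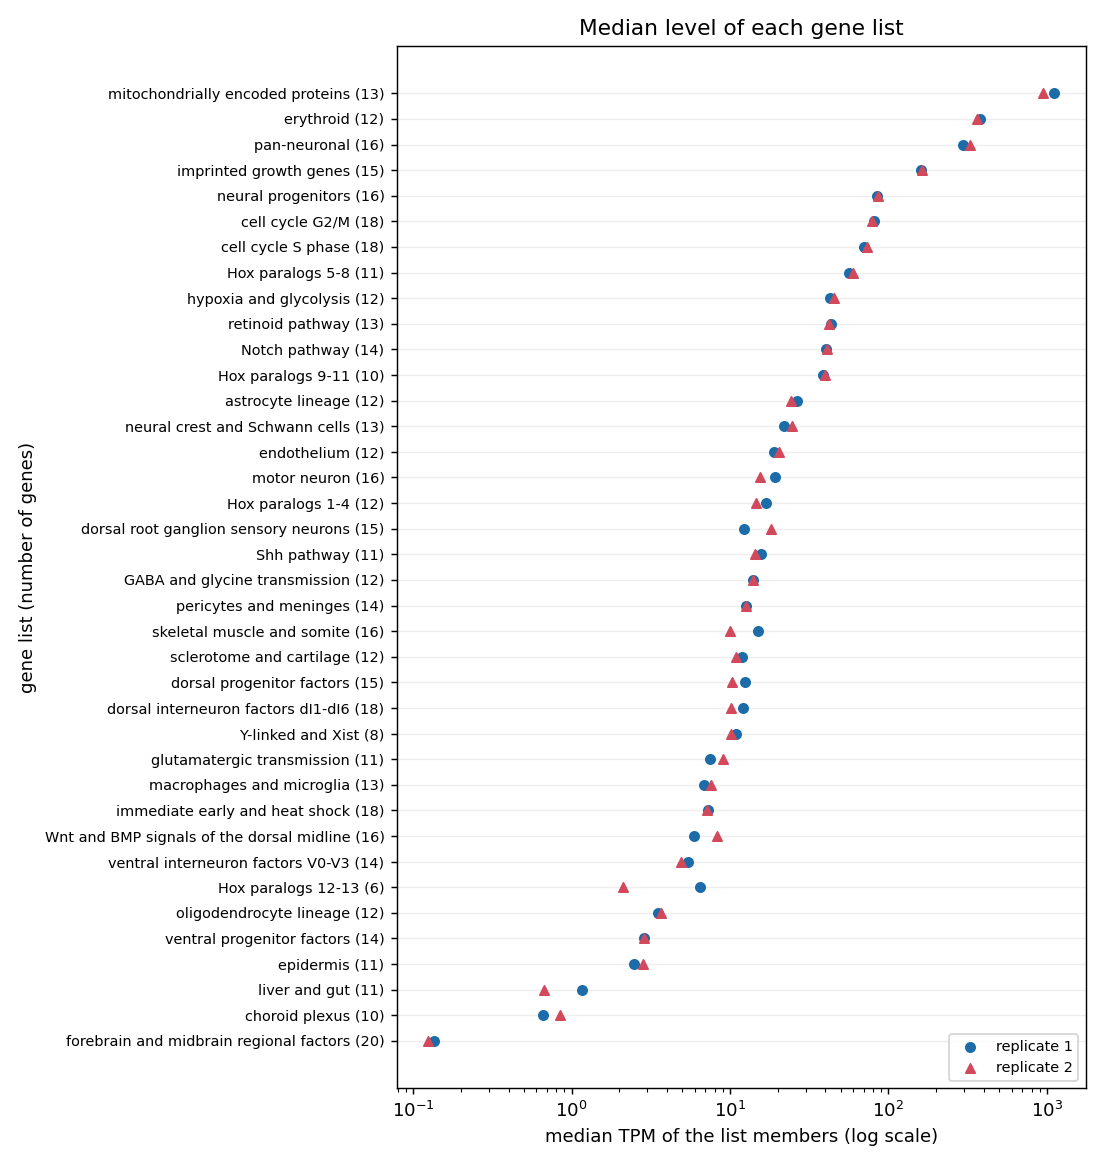
Median TPM of each of the 38 gene lists on a log axis, with circles for replicate 1 and triangles for replicate 2 and the number of genes in brackets. The pan-neuronal list lies near 313 TPM and the neural progenitor list near 84.9 TPM, while the forebrain and midbrain factors lie at 0.13 TPM.

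The libraries agreed closely for most genes. Over 15735 genes with a mean of at least 1 TPM, Pearson's r of log2(TPM + 1) was 0.987 and Spearman's rho 0.990, both across genes, which are not independent replicates. As a check only against 1 library deposited again under another name, the counts differed by more than sampling noise, with a chi-square of 7.35 per degree of freedom over 17642 genes. The biological coefficient of variation was 6.75% by edgeR. The SD of the log2 ratio was 0.53 among genes at 1 to 5 TPM and 0.11 at 100 TPM or more. In total 225 genes (1.43%) were over 2-fold apart, 94 higher in replicate 2 and 131 higher in replicate 1, and 189 of them lay at 1 to 5 TPM. By TMM-scaled CPM, also with 1 added, 28 genes were over 2-fold apart. CPM is not corrected for length, so the added 1 weighs differently on short genes and these counts are not on a like scale. Only 20 of 13517 protein-coding genes were over 2-fold apart, and the deposited TPM intervals of 15 of the 225 did not overlap. Over all levels of change, the intervals of 2249 genes (14.3%) did not overlap. The deposited intervals do not always hold the TPM value used here, as for Fabp7 in replicate 1 (1469 TPM, interval 1407 to 1446).

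The pools differed in gene groups from the tail end of the axis, muscle and sensory ganglia. A list's median log2 ratio (replicate 2 over replicate 1) was placed among 10000 random lists matched on level, as a description of these 2 libraries. Of 38 lists, 11 had a percentile outside the middle 95%, where 1.9 would be expected if genes varied independently. In simulated libraries, where genes also varied independently, 7.5% of 200 unchanged lists fell outside. Members of a real list may vary together and some lists share genes, so neither rate is the chance rate of these lists. Hox paralogs 12-13 were lowest in replicate 2, with a median of -1.04 and all 5 members above a mean of 1 TPM lower (percentile 0). Hoxb13 (ENSMUSG00000049604, chromosome 11, 96194316 to 96197447) had 6.28 TPM in replicate 1 and 0.87 TPM in replicate 2. Its log2 count ratio was -2.88 (95% exact binomial interval -3.41 to -2.38, counting error only). Hoxc13 (ENSMUSG00000001655, chromosome 15, 102921103 to 102928814) had 14.6 and 5.39 TPM, and its log2 count ratio was -1.47 (-1.68 to -1.26). Paralogs 1-4 were lower in replicate 2 for 12 of 12 genes (median -0.20, percentile 0) and paralogs 9-11 for 7 of 10 (-0.19, percentile 0). Paralogs 5-8 were split, 6 higher and 5 lower (0.00, percentile 18.1).

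Muscle and somite genes were lower in replicate 2 for 13 of 15 members (median -0.36, percentile 0), among them the actins Actc1 (131 and 88.0 TPM in replicates 1 and 2) and Acta1 (64.0 and 46.1 TPM). Retinoid pathway genes (-0.11, percentile 0.07) and the 5 tested liver and gut genes (-0.40, percentile 0.495) were also lower. Sclerotome and cartilage genes lay on the limit, with 7 of 9 lower (-0.08, percentile 2.5). Sensory ganglion genes were higher in replicate 2 for 14 of 15 members (0.33, percentile 100). Its members Isl1, Pou4f1 and Prph also stand in the interneuron or motor neuron lists. Avil, an actin-binding protein of sensory neurons (ENSMUSG00000025432, chromosome 10, 127000709 to 127020994), had 4.30 and 8.24 TPM, and Prph had 84.2 and 132 TPM. Neural crest and Schwann cell genes (0.19, percentile 99.96), pan-neuronal genes (0.11, percentile 99.97) and dorsal midline Wnt and BMP signals (0.15, percentile 97.96) were higher as well. Motor neuron genes went both ways, 10 higher and 6 lower, with a median of 0.14 (percentile 99.08) but a mean of 0.00. Their shift was not seen once members of other shifted lists were left out (median 0.04, percentile 46.4, an alternative added after seeing the data). The motor neuron factor Lhx4 was lower in replicate 2 (18.5 and 10.1 TPM), and Mnx1, chosen after its values were seen, likewise (8.46 and 5.73 TPM). Neural progenitor, S phase, G2/M and erythroid lists lay inside the middle 95%.

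**Figure D3:**
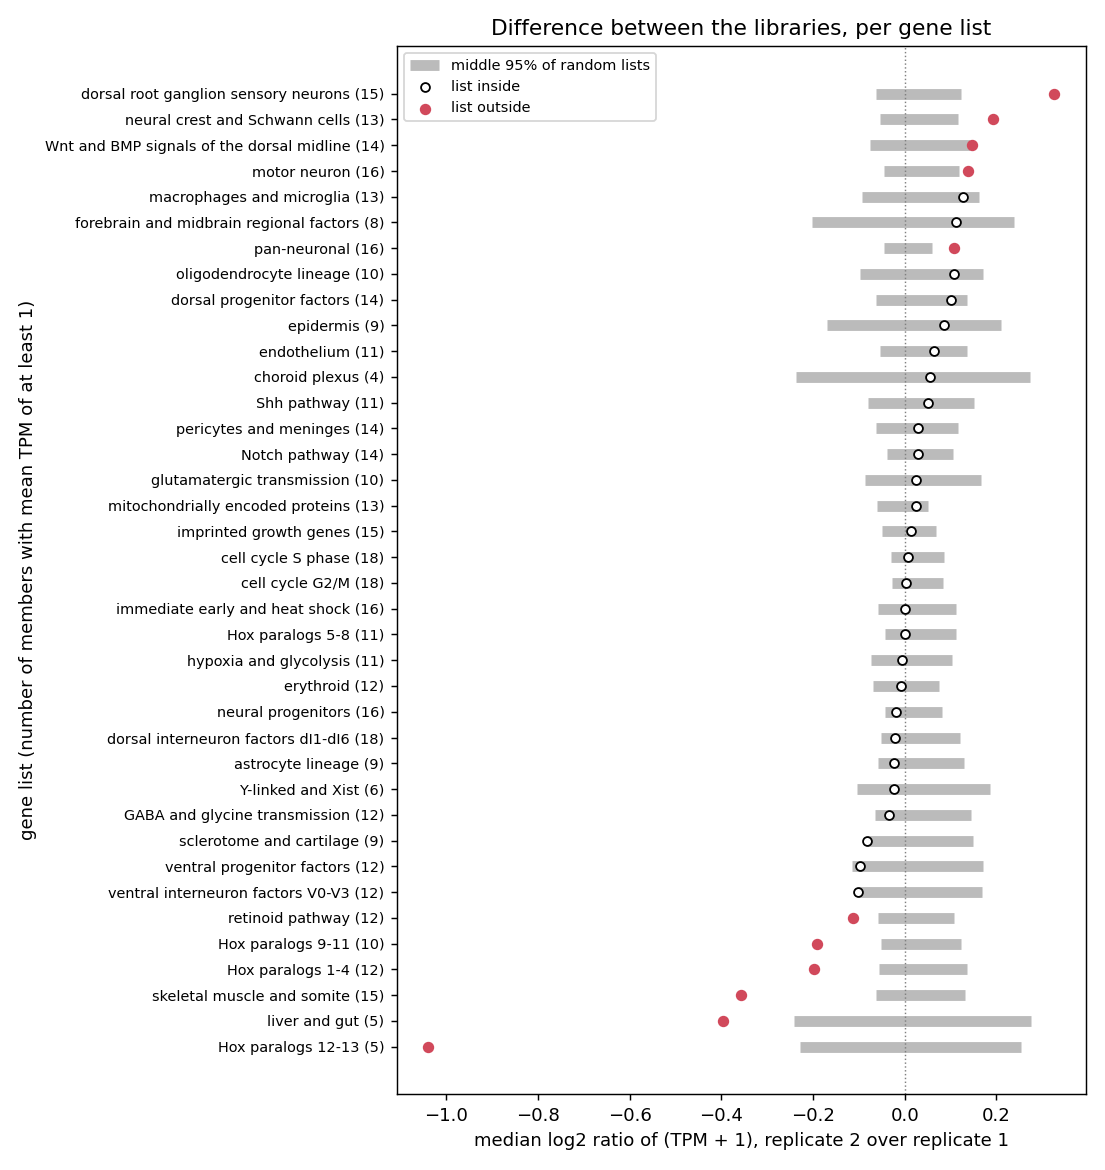
Median log2 ratio of (TPM + 1), replicate 2 over replicate 1, of each of the 38 gene lists, with the number of members tested in brackets and grey bars for the middle 95% of 10000 random lists. Filled points are the 11 lists whose percentile lies outside the middle 95%, from Hox paralogs 12-13 at -1.04 to sensory ganglion genes at 0.33, and sclerotome and cartilage genes lie at the edge of their bar.

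Among protein-coding genes with a mean of at least 5 TPM and 100 counts in the higher library, the 8 lowest in replicate 2 by TPM ratio were Hoxc13 (-1.29), Gm9803 (-1.16), Hist1h1b (-0.95), Hist1h2ai (-0.93), Hist1h2ae (-0.85), Ccdc8 (-0.84), Lhx4 (-0.82) and Pgam2 (-0.76), a muscle enzyme. The 8 highest were mt-Nd4l (2.22), Avil (0.80), the homeobox gene Hmx1 (0.79), the neuropeptide gene Gal (0.79), Gm20721 (0.78), Gm3055 (0.78), Ppp1r1c (0.74) and Rpl10-ps3 (0.71). mt-Nd4l overlaps mt-Nd4, Hist1h2ai and Hist1h2ae have near-identical copies, and Gm9803, Gm20721, Gm3055 and Rpl10-ps3 are predicted genes or copies of other genes, so the ratios of these are uncertain. These genes were picked for their size, which overstates their ratios.

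Transcript use was compared through the deposited percentage of each gene's transcripts. The most abundant transcript differed between the libraries in 614 of 8304 genes (7.39%) with several transcripts and at least 5 TPM. It differed in 7 of 4664 genes where it held at least 60% in both. All 30 genes of a fixed isoform set were expressed, 27 with the same leading transcript, and the remaining 3, chosen after their values were seen, were Gria2, Meis2 and Dnm1. Pkm, the glycolytic enzyme pyruvate kinase, has a pair of mutually exclusive exons. The downstream one (chromosome 9, 59675568 to 59675734), of the form typical of dividing cells, was in 71.5 ± 0.106% of its transcripts and the upstream one (59675029 to 59675195) in 28.5 ± 0.106%. For the neurotrophin receptor gene Ntrk2, transcript Ntrk2-202, with a coding length of 476 codons, held 68.0 ± 0.509%, and Ntrk2-201, of 821 codons, held 32.0 ± 0.509%. Transcripts with the alternative 42-nucleotide exon of Pax6 (chromosome 2, 105684751 to 105684792) held 16.0 ± 3.46%. Among guidance and splicing genes, Robo3-202 held 61.5 ± 0.735% of Robo3, Dclk1-203 held 58.0 ± 1.47% of Dclk1, Rbfox2-203 held 68.0 ± 1.77% of Rbfox2 and Cdc42-202 held 74.9 ± 0.898% of Cdc42.

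By RNA class, nuclear protein-coding genes other than histone and ribosomal protein genes held 90.1 ± 0.423% of expected counts, noncoding genes 3.81 ± 0.233%, spike-in controls 3.02 ± 0.0746%, ribosomal protein genes 1.61 ± 0.0306% and mitochondrial genes 1.05 ± 0.0506%. Replication-dependent histone genes held 0.122% in replicate 1 (95% exact binomial interval 0.120 to 0.123%) and 0.0999% in replicate 2 (0.0989 to 0.101%), intervals that cover counting error only.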

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

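No test in this part was chosen only after the result was seen. Number-named rows and gene rows without a name entered none of the gene lists but carried counts. Their sums exceeded the floor of 3 counts. That floor holds for a single row, so this shows only that these rows were not empty. The gene rows without a name did enter the gene counts, and 110 of them were among the 15181 genes detected. The short rows named by number (median length 73 nucleotides) held 37.59 expected counts in replicate 1 and 31.58 in replicate 2. The 884 gene rows without a name in the reference held 95030 expected counts in replicate 1 and 91252.9 in replicate 2. Of these, ENSMUSG00000100725 had 20589 and 24297 counts, ENSMUSG00000052429 had 8612 and 8177, and ENSMUSG00000103057 had 18585 and 9675, or 858 and 430.4 TPM. These 3 rows were chosen for their size after their values were seen.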

How the results depend on the processing

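The alternatives that leave out members of other shifted lists or of neural lists, and those on single named genes, were chosen only after the data were seen. No list comparison, no shifted list and none of the 16 genes named for the largest ratios changed direction under the alternatives run on it, and ratios of other named genes were not counted here. Of the lists inside the middle 95%, 7 with medians above 0 had medians of -0.04 to -0.01 in TMM-scaled CPM, and oligodendrocyte genes had -0.02 without members of shifted lists. Leaving out either replicate moved no count by over 1.5 times. It moved the share of Hox paralogs 12-13 from 2.00% to 1.19% without replicate 1 and 2.82% without replicate 2. For means over both libraries it gives the value of the other library, which by construction lies within 1 SD, so it says nothing of their stability. In all, 76 settings kept such main results within these limits and 47 moved one. The 76 include the settings that left a replicate out of a mean, which could not move, so they overstate stability. The cause of the moves was not tested except where the setting itself removes or adds genes. Genes at 1 to 5 TPM, the least deeply counted, held 189 of the 225 genes over 2-fold apart, and depth itself was not varied.

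Transcripts detected numbered 50117 at 0.1 TPM and 16643 at 5 TPM. Pearson's r across genes was 0.965 with a pseudocount of 0.1, 0.929 with 0.01, 0.992 with no filter on low values, 0.990 at a mean of at least 5 TPM, 0.996 in TMM-scaled CPM and 0.990 in FPKM. Genes over 2-fold apart numbered 361 with a pseudocount of 0.1, 396 with 0.01, 381 with no filter and 36 at a mean of at least 5 TPM. They numbered 28 each in CPM scaled by TMM and by DESeq2, where the same pseudocount is not on a like scale with TPM.

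The difference of Hox and forebrain and midbrain medians was 6.92 with a pseudocount of 0.1, 3.71 by list means, 4.04 in FPKM and 3.31 over members at 1 TPM or more in a library. That of neuronal and progenitor genes was 1.36 by list means and 0.96 in CPM. That of dorsal and ventral progenitor factors was 1.94 with a pseudocount of 0.1 and 1.14 by list means. For dorsal and ventral interneuron factors it was 1.08 with a pseudocount of 0.1, 1.31 by list means, 0.90 in FPKM, 1.20 in CPM, 0.87 over members at 1 TPM or more and 1.26 without the shared member. For astrocyte and oligodendrocyte genes it was 2.65 with a pseudocount of 0.1, 1.16 by list means, 2.24 in FPKM, 2.73 in CPM and 3.10 over members at 1 TPM or more.

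By expected counts, Hox paralogs 1-4 held 23.6%, paralogs 5-8 held 38.3% and paralogs 9-11 held 36.0% of the Hox total. Genes with differing leading transcripts numbered 974 at a gene TPM of at least 1, 293 at 20 or more, and 7 with a leading share of at least 60%. By TPM in place of counts, shares were 75.5% for other protein-coding genes, 9.67% for noncoding, 7.34% for spike-in, 4.44% for ribosomal protein, 2.30% for mitochondrial, 0.427% for histone, 0.317% for unmatched and 0.00182% for number-named rows.

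All 11 shifted lists stayed outside the middle 95% in TMM-scaled CPM, with a pseudocount of 0.1 and with 10 bins. TMM-scaled CPM added 4 lists lower in replicate 2, ventral progenitor (-0.18), dorsal interneuron (-0.09), ventral interneuron (-0.14) and sclerotome (-0.18), and a pseudocount of 0.1 added ventral interneuron factors (-0.13). Leaving out members of other shifted lists kept 10 of the 11, without motor neuron genes (0.04). Of the settings on single lists and genes, 568 stayed within the limits. They include those leaving a replicate out of a named gene's mean TPM, which could not move. The 5 added and 1 lost calls are those above, and 4 settings moved. These are the members detected at 5 TPM, which were 9 for sensory ganglion, 2 for epidermis, 1 for liver and gut and 2 for choroid plexus.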

Other observations

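Medians of log2 count ratios in this part are over list members with a mean of at least 10 expected counts. The tests of limb bud genes, of all neurons, of S phase genes and of other RNAs without poly(A) tails, and the subsets of members under 5 TPM, were chosen only after the results they bear on were seen. For tail bud and S phase genes the interval lay below 0 but far from the shift to be explained. A rule that this distance decides was set only after the values were seen, and no conclusion is drawn from it here.

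Imprinted growth genes were among the highest lists, with a median of 161 ± 2.09 TPM and all 15 detected. Meg3, a maternally expressed noncoding RNA, stood at 907 ± 6.42 TPM and the cell cycle inhibitor Cdkn1c at 840 ± 22.6 TPM. Notch pathway genes had a median of 40.5 ± 0.410 TPM (14 of 14 detected), led by Hes5 and the feedback regulator Nrarp (78.3 ± 0.198 TPM). Retinoid pathway genes had a median of 42.8 ± 0.707 TPM (12 of 13), led by the binding proteins Crabp1 (583 ± 70.4 TPM) and Crabp2 (321 ± 18.3 TPM). Shh pathway genes had a median of 15.005 ± 0.841 TPM (11 of 11), led by Gas1 (133 ± 9.23 TPM) and Sufu (29.9 ± 0.566 TPM). Dorsal midline Wnt and BMP signals and targets had a median of 7.11 ± 1.68 TPM (14 of 16), led by the BMP targets Id3 (271 ± 3.74 TPM) and Id1 (86.8 ± 2.36 TPM).

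Cell cycle genes were all detected, with medians of 79.9 ± 1.20 TPM for 18 G2/M genes (Ube2c 269 ± 16.2, Cdk1 183 ± 1.85 TPM) and 71.8 ± 1.72 TPM for 18 S phase genes (Rrm2 216 ± 0.530, Mcm7 163 ± 1.40 TPM). Hypoxia and glycolysis genes had a median of 43.9 ± 1.88 TPM (11 of 12), led by Ldha (732 ± 46.1 TPM) and Aldoa (394 ± 0.417 TPM). Immediate early and heat shock genes had a median of 7.19 ± 0.0955 TPM (16 of 18), led by Hsp90aa1 (939 ± 4.94 TPM) and Jund (101 ± 5.78 TPM). In these pools of both sexes the Y-linked gene Eif2s3y was at 28.1 ± 3.42 TPM and Xist at 22.1 ± 0.799 TPM (6 of 8 genes of that list detected, median 10.6 ± 0.541 TPM). The 13 mitochondrially encoded protein genes had a median of 1026 ± 122 TPM, led by the overlapping genes mt-Atp6 (5022 ± 102 TPM) and mt-Atp8 (4908 ± 58.8 TPM).

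Hox paralogs 12-13 were lower in replicate 2 in all 6 genes, with a median log2 count ratio of -1.80 (95% bootstrap interval over genes -3.23 to -0.93), and for the 5 with a mean of at least 1 TPM the median TPM ratio (-1.04) lay at percentile 0.01 among random lists also matched on GC content and length, which argues against those biases. Tail bud and presomitic genes were lower by less, with a median of -0.20 (-0.27 to -0.11, 11 of 12 lower), and the 10 of them under 5 TPM likewise (-0.20, -0.39 to -0.13). Members under the count minimum were left out. Of these, Fgf17 (6 and 1 counts) and Fgf8 (2 and 1) were lower in replicate 2, Hes7 had 8 and 8, and Msgn1 and Cdx4 had 0 in both. The whole interval of the tail bud list lay below 0, as less such tissue would give, but far from the Hox shift. The members left out had few or 0 counts in both libraries, and those kept need not follow tail bud tissue alone. This distance therefore cannot decide on less tail bud mesoderm as a cause. A difference of the size of the tail bud one was not particular to caudal genes, since anterior Hox paralogs 1-4 had a median log2 TPM ratio of -0.20 (12 of 12 lower). Muscle and somite genes were lower as well (median log2 TPM ratio -0.36, 13 of 15 lower), and a cause shared with the Hox genes was not tested. Limb bud tissue stays open. The 11 limb genes that met the count minimum had a median of -0.04 (-0.13 to 0.07), but several are also expressed in neural tissue. Over the 5 of these under 5 TPM and in none of the 38 lists, the median was -0.125 (-2.01 to 0.10, 3 lower and 2 higher). Among these 5, Pitx1 had 77 and 20 counts and Tbx4 29 and 19. Tbx5 (6 and 0 counts) and Hand2 (12.97 and 5), also under 5 TPM and in none of these lists, did not meet the minimum. Both were lower in replicate 2, so the subset leaves out members that go with less limb tissue. A shorter caudal end of the neural tube in replicate 2 is a candidate explanation that was not tested, and the design names no biological difference between the pools.

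Sensory ganglion genes were higher in replicate 2 and stayed at percentile 100 among lists matched also on GC content and length, which argues against those biases. Their median exceeded the pan-neuronal one by 0.27 (0.11 to 0.49), which argues against more neurons of every kind as the whole cause. A second list of 14 sensory ganglion genes, fixed before its values were seen and holding no gene of the first, was higher by a median of 0.37 (0.25 to 0.65, 12 of 14 higher), among them Prdm12 (30.8 and 44.9 TPM), P2rx3 (32.98 and 42.2 TPM) and Gfra3 (16.9 and 23.6 TPM). A larger share of ganglion tissue in replicate 2 may therefore account for the pattern, as a hypothesis found and tested on the same libraries. Some of these genes are also expressed in the spinal cord, and 1 of the 14, Shox2, is in the limb bud list.

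Replication-dependent histone genes were lower in replicate 2 in 47 of 55 genes, with a median log2 count ratio of -0.50 (-0.59 to -0.35). Their summed counts over 67 genes were lower too (-0.29, exact binomial interval -0.31 to -0.27, counting error only). This argues against reads divided otherwise among these genes as the whole cause. Copies outside this set were not counted. S phase genes had a median of -0.0378 (-0.11 to -0.01), below 0 but far less than the histone shift. How far this list would fall with fewer S phase cells is not known here, so the distance cannot decide on that cause. By TPM ratio the S phase list had a median of 0.00648, with 10 members higher and 8 lower. Other RNAs without poly(A) tails had a median of 0.0709 (-0.34 to 0.24) over 7 genes, 3 lower and 4 higher, among them Rn7sk (-0.35) and Rpph1 (-0.34) and the most abundant, the near-identical Rn7s1 (-0.04) and Rn7s2 (0.07). A lower yield of such RNA cannot be told apart from other explanations with so few genes that go both ways.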
